A study of Drosophila melanogaster with 15 samples.

How the data were processed

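RNA from nuclei of the mushroom body, the learning and memory centre of the fly brain, was sequenced from male Drosophila melanogaster. Nuclei were purified with INTACT, an affinity method that pulls down nuclei carrying a tagged nuclear envelope protein, here the GFP-tagged protein UNC84 under the R14H06-Gal4 driver. The same driver expressed an RNAi hairpin against Bap60 or, as the control, against mCherry. Per the labels' protocols, flies were kept at 25°C and 70% humidity, RNA was extracted with the PicoPure kit and libraries were made with the Nugen Ovation system for Drosophila. Juvenile flies were 0 to 3 hours past eclosion and mature flies 1 to 5 days old. The labels give 2 juvenile knockdown, 3 juvenile control, 5 mature knockdown and 5 mature control libraries. They do not say whether the libraries of a group came from separate sets of flies, so p-values measure the spread between these libraries, which may in part be technical.

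The deposited files hold whole-number read counts per gene that the authors did not normalize, as the values show. Reads were aligned with STAR 2.5.3a to the BDGP6 build and counted with HTSeq 0.7.1, per the submitters' processing notes. The strand setting, the counting mode and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart, and 32 of the 88 named genes share positions with another gene. All 15 files listed the same 17559 gene IDs in the same order. Names and positions came from annotation release 115 on assembly BDGP6.54, which gave a symbol to 17253 IDs and none to 306. HTSeq's entries for reads outside genes (1.1% to 2.84%) and for ambiguous reads (7.08% to 7.69%) stayed out of library sizes and tests. These are shares of the sum of gene, outside-gene and ambiguous counts. An entry for the UNC84 tag was listed in the 10 mature files only and also stayed out. No pair of libraries within a group was a duplicate, since the lowest chi-square per degree of freedom between replicates was 15.8.

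Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, which left 11997 genes. Libraries were scaled by TMM, and 1 mean per group was fitted over all 15 libraries with robust quasi-likelihood dispersions. Each of 5 contrasts was tested with edgeR's quasi-likelihood F-test and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Values per library are CPM on the TMM scale, given as mean ± SD, and every adjusted p is from this test unless another tool is named. The contrasts were knockdown against control at each age, the difference of these effects, and mature against juvenile flies within each genotype. The design, the alternatives, the gene lists and the rule for named genes were set before the data were examined.

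The rule named Bap60 always. Among called genes with a mean of at least 5 CPM in a compared group, it took the 7 largest and 7 smallest log2 fold changes among genes with a proper name, the 2 largest and smallest of any name, and up to 3 called members of each list. The text names a subset of these. The 25 lists were SWI/SNF subunits, learning and memory genes, synaptic machinery, voltage-gated and leak channels, neurotransmitter receptors, neuropeptides, axon guidance and adhesion, ecdysone response and neuronal remodelling, activity-regulated genes, circadian clock genes, antimicrobial and immune genes, stress response genes, cell death and DNA damage genes, neuroblast and cell cycle genes, cuticle proteins, odorant-binding proteins, cytosolic ribosomal proteins, mitochondrially encoded genes, nuclear-encoded oxidative phosphorylation genes, and markers of Kenyon cells, glia, photoreceptors, fat body, muscle and other neurons. Lists were tested with camera in limma 3.58.1, two-sided, with a preset correlation of 0.01, and again with an estimated correlation and with fry. Adjustment ran over the 25 lists of a comparison. The name pattern for cuticle proteins also took Cp190, Cp110 and chorion proteins, and a test without them was added later.

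The alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, RLE and upper-quartile scaling, no filter, a stricter filter (a mean count of 10 and 1 CPM in 5 libraries), a fit on the compared groups alone, the replicate number as a block, 1 surrogate variable from sva 3.50.0, a test against a 1.2-fold change, an adjusted p under 0.01, and leaving out each library. Voom weights by age and the Kenyon cell marker level as a covariate were added after the data had been seen. Single values were compared with two-sided exact permutation tests.

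The procedure was tested on simulated data, with 200 changed genes in each of 3 runs drawn from the real means and library sizes. When each age kept its own spread, the fit on all 15 libraries recovered 60.3% of 2-fold and 93% of 4-fold changes in the juvenile comparison over 11364 genes, but 56.6% of its calls were unchanged genes. A fit on the juvenile libraries alone, over 10686 genes, recovered 46% and 82.3%, with 11.5% false calls. In the mature comparison the fit on all libraries recovered 80% and 98%, with 4.5% false calls, and in the difference between ages 31.4% of calls were false. With no effect simulated in 5 runs, at most 127 genes were called in the juvenile and 1 in the mature comparison, and at most 1 list. Genes were drawn independently in these runs. Members of the real lists were correlated, with estimates such as 0.822 for Kenyon cell markers and 0.589 for synaptic machinery in the juvenile comparison. The runs therefore do not show how often camera with the preset correlation calls unchanged lists in real data.

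Total gene counts ran from 17447070 to 70495790 per library. Bap60, a gene of low level here, had 208 to 1239 counts per library, so counting error was small beside the spread between libraries. Intervals and limits from counts would cover counting error only. GC content was not analysed here.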

Results

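The series measured nuclear RNA of mushroom body neurons (Kenyon cells) in 15 libraries, and asked how Bap60, a core subunit of the SWI/SNF chromatin remodelling complex, bears on gene expression in the memory centre of the fly brain. RNAi against Bap60 was compared with RNAi against mCherry in juvenile males (2 knockdown and 3 control libraries) and in mature males (5 and 5). The groups differed in the hairpin expressed. Any other difference that came with the hairpins cannot be told apart from loss of Bap60, so a knockdown effect below means a difference between these groups. Total gene counts were 45547974 and 53143845 in the juvenile knockdown libraries and 37879789 to 45731087 in the juvenile controls. They were 17447070 to 37563455 in the mature knockdown libraries and 18173548 to 70495790 in the mature controls.

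Mature libraries resembled each other closely, with Spearman correlations across genes of 0.9769 to 0.9897 within the knockdown group and 0.9758 to 0.9881 within the controls. Juvenile libraries were more variable, at 0.9525 between the knockdown libraries and 0.9294 to 0.9549 between controls. The biological coefficient of variation was 0.85 in juvenile and 0.22 in mature libraries. Juvenile controls 1 and 3 lay at opposite ends of the second principal component (−99.3 and 96.1), and control 1 had the lowest sample weight in limma-voom (0.23).

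**Figure D1:**
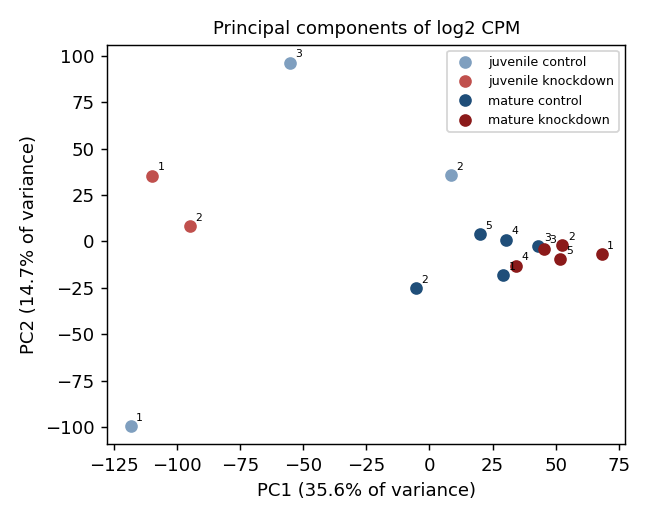
Principal components of log2 CPM, with each point 1 library (first component 35.6% and second 14.7% of the variance). Mature libraries lie close together, while the juvenile libraries spread widely, with juvenile controls 1 and 3 at −99.3 and 96.1 on the second component.

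Bap60 (FBgn0025463; chromosome X, 13157445 to 13159508, minus strand, BDGP6.54) was lower in mature knockdown libraries, at 11.2 ± 2.69 CPM (SD, n = 5) against 17.3 ± 2.61 CPM in controls (n = 5), and each of the 5 knockdown libraries lay below every control. The 1.57-fold difference (log2 −0.65) gave p = 0.0079 in a two-sided exact permutation test, the smallest p that 5 against 5 allows. In juvenile flies Bap60 was at 6.33 ± 1.84 CPM (n = 2) against 9.49 ± 3.76 CPM (n = 3), a 1.43-fold difference (log2 −0.52) with an exact permutation p = 0.3, where the design cannot go below 0.1. Control 2 of the juvenile group, at 5.15 CPM, lay between the knockdown libraries at 5.03 and 7.63 CPM. After adjustment over 11997 genes, edgeR did not call Bap60 in mature (log2 −0.63, SE 0.23, adjusted p = 0.719) or juvenile flies (log2 −0.58, SE 0.33, adjusted p = 0.331).

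**Figure D2:**
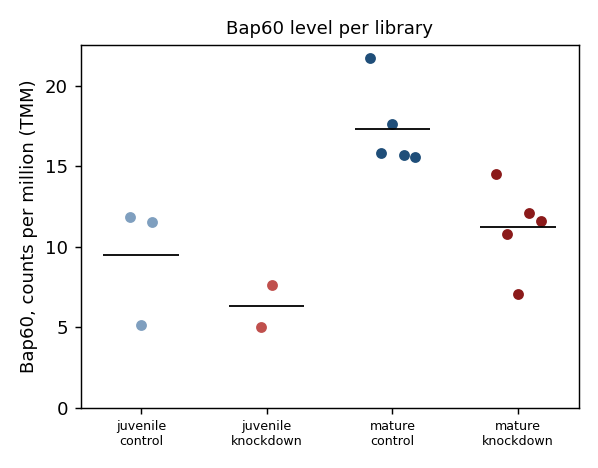
Bap60 level in CPM for each library by group, with points for libraries and bars for the group mean. All 5 mature knockdown libraries (7.08 to 14.49 CPM) lie below the 5 mature controls (15.6 to 21.72 CPM), while the juvenile groups overlap.

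In mature flies, the question was which genes differ between Bap60 knockdown and control libraries. Ldh, the lactate dehydrogenase that interconverts pyruvate and lactate, fell to 57 ± 15.3 CPM from 255 ± 78.7 CPM, a 4.48-fold decrease (log2 −2.16, SE 0.25, adjusted p = 0.00294). Gadd45, a stress-response gene, fell from 40.7 ± 3.05 to 16.6 ± 2.11 CPM (log2 −1.30, SE 0.18, adjusted p = 0.00334). The bHLH-PAS transcription factor gene dysf fell from 30.3 ± 12 to 11.8 ± 1.3 CPM (log2 −1.36, SE 0.21, adjusted p = 0.0139), and the transporter gene MFS3 from 51.8 ± 17.8 to 17.1 ± 5.48 CPM (log2 −1.60, SE 0.26, adjusted p = 0.0242). The forkhead gene Crg-1 rose from 7.5 ± 0.985 to 18.3 ± 3.29 CPM (log2 1.28, SE 0.15, adjusted p = 0.00119), and Xxylt, which encodes a xylosyltransferase, from 49.9 ± 5.15 to 84.2 ± 12.9 CPM (log2 0.75, SE 0.12, adjusted p = 0.0139). The noncoding RNA gene lncRNA:CR43753, chosen after its values were seen, fell from 3.37 ± 0.913 to 0.225 ± 0.23 CPM (log2 −3.89, SE 0.63, adjusted p = 0.0161, and −4.58 without mature knockdown 4).

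These 7 genes, 2 higher and 5 lower, were all that edgeR called in mature flies. Each was separated completely between the 5 knockdown and 5 control libraries, an outcome that chance gives for 0.794% of unselected genes. They were chosen by their test between the same libraries, so the separation is no further support. Before adjustment 693 genes had p under 0.05, DESeq2 called 47 genes (19 higher and 28 lower) and limma-voom with sample weights 114. Ldh, Gadd45 and Crg-1 kept their calls with any library left out. MFS3 lost its call without juvenile control 2 (adjusted p = 0.0519) or 3 (0.0631), mature control 2 (0.0607), 3 (0.0914) or 5 (0.0661), or mature knockdown 2 (0.0667), 3 (0.0968), 4 (0.109) or 5 (0.138). Leaving out mature control 3 ended the calls of Xxylt (0.0914), dysf (0.0631) and lncRNA:CR43753 (0.068), and mature knockdown 5 did the same (0.0627 for each). Mature knockdown 4 ended those of Xxylt (0.0573) and dysf (0.0573), mature knockdown 3 those of dysf (0.0668) and lncRNA:CR43753 (0.0678), and mature controls 2 (0.0607) and 5 (0.0656) and knockdown 2 (0.0667) that of lncRNA:CR43753. The number of called genes was 11 without juvenile control 1, 3 without mature control 3, 4 without mature knockdown 4 and 3 without mature knockdown 5. MFS3 was also not called with upper-quartile scaling (adjusted p = 0.0607) or in a fit on the mature groups alone (0.0623).

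The genes lie on BDGP6.54 at chromosome 3L 6259105 to 6262694 (Ldh, FBgn0001258), 2R 7249161 to 7250655 (Gadd45, FBgn0033153), 3R 26076592 to 26098711 (dysf, FBgn0039411), 2L 1143201 to 1147395 (MFS3, FBgn0031307), X 3793223 to 3797339 (Crg-1, FBgn0021738), 2R 24022343 to 24023981 (Xxylt, FBgn0034959) and 2L 2271319 to 2279714 (lncRNA:CR43753, FBgn0264084). MFS3, dysf and Crg-1 each overlap 1 gene on the same strand and Crg-1 also 1 on the other, so their counts are uncertain.

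**Figure D3:**
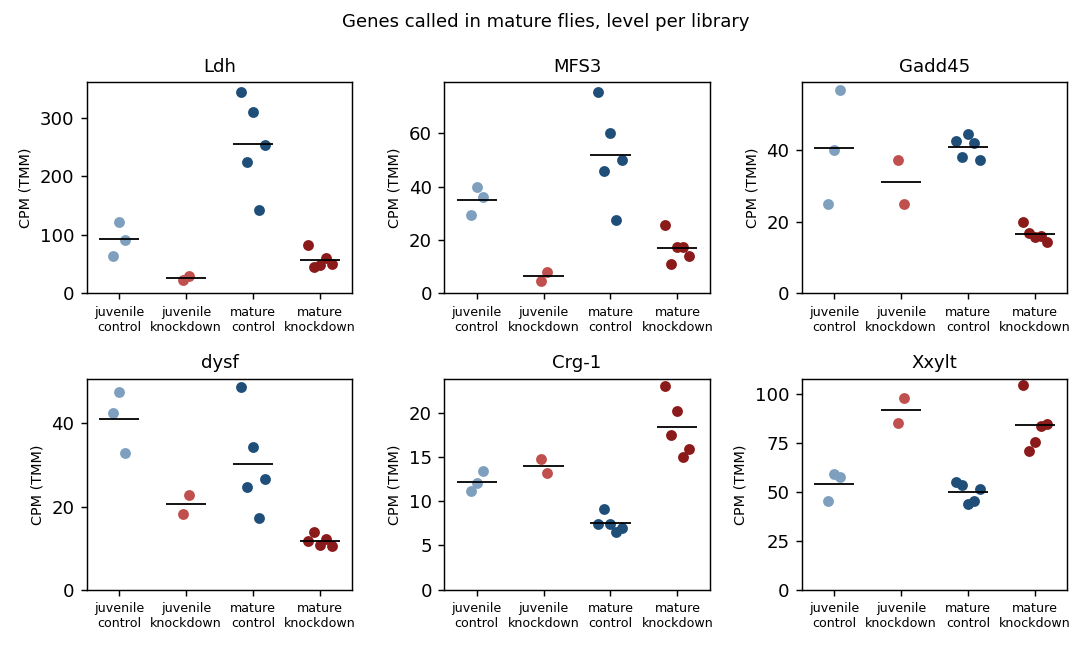
CPM of Ldh, MFS3, Gadd45, dysf, Crg-1 and Xxylt in each juvenile and mature library by group, on a linear axis. Points are libraries and bars the group mean, and lncRNA:CR43753 is not shown. Mature knockdown and mature control libraries do not overlap for any of these genes, as for Ldh at means of 57 and 255 CPM.

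Some neuronal gene groups lay slightly higher in mature knockdown flies, though none of the tests below held with an estimated correlation. Neurotransmitter receptors (median log2 0.16 over 34 genes, adjusted p = 5.06e-07), voltage-gated and leak channels (0.12, 26 genes, 3.36e-06), synaptic machinery (0.13, 29 genes, 6.86e-06), axon guidance and adhesion genes (0.08, 41 genes, 1.08e-05) and learning and memory genes (0.10, 27 genes, 6.81e-05) ranked above other genes in camera. With an estimated correlation the adjusted p = 0.416 for receptors and 0.448 for the other groups. Neuropeptides (adjusted p = 6.98e-07) gave adjusted p = 0.0684 with an estimated correlation, and markers of other neurons (median 0.31, 4.60e-06) adjusted p = 0.227. No single member passed over all genes. Adjusted over the list alone, 3 neuropeptide genes and 2 receptor genes were higher, and 4 of the 11 markers of other neurons were higher and 1 lower.

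Immune genes (adjusted p = 2.64e-06), photoreceptor markers (1.14e-04), oxidative phosphorylation genes (0.0023) and glial markers (0.00399) also ranked higher, with adjusted p = 0.258, 0.416, 0.729 and 0.448 with an estimated correlation. Stress response genes (1.17e-04), cuticle proteins (0.00261) and cell death genes (0.0282) ranked lower, with adjusted p = 0.416, 0.448 and 0.258 with an estimated correlation. Adjusted over the list alone, 1 stress gene was higher and 2 were lower, and 1 immune gene and 1 clock gene were lower. Kenyon cell markers (adjusted p = 0.065), ribosomal protein genes (0.093), ecdysone response and remodelling genes (0.385), activity-regulated genes (0.403) and SWI/SNF subunits (0.861) did not pass. Kenyon cell markers did pass with RLE scaling (0.046) and without mature control 1 (0.00247), 3 (8.87e-04) or 5 (0.0335) or mature knockdown 2 (0.0023), 4 (0.00492) or 5 (0.025), and ribosomal protein genes without mature control 2 (8.44e-04) or 4 (0.0144) or mature knockdown 3 (4.25e-07) or 5 (0.0331). Their medians were 0.02 and 0.03, and with an estimated correlation adjusted p = 0.795 and 0.837. Oxidative phosphorylation genes lost their call without mature control 1 (0.428) or mature knockdown 2 (0.913), glial markers without mature control 1 (0.21), cuticle proteins without mature knockdown 1 (0.103), and cell death genes without mature control 3 (0.098) or 4 (0.0509) or mature knockdown 5 (0.12).

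In juvenile flies, the genes lower after Bap60 knockdown included 7 of 29 genes of the synaptic machinery. The synaptic vesicle genes Syngr (601 ± 58.7 to 258 ± 46.3 CPM, log2 −1.22, SE 0.18, adjusted p = 0.00165), Syt4 (log2 −0.90, adjusted p = 0.00351) and Csp (log2 −0.59, adjusted p = 0.0113) fell, as did the Na,K-ATPase subunit gene nrv2 (log2 −0.90, adjusted p = 0.00177). The neuropeptide gene sNPF fell from 1020 ± 169 to 458 ± 6.93 CPM (log2 −1.15, SE 0.22, adjusted p = 0.00743) and AstC by 1.33 on the log2 scale (adjusted p = 0.0112). Among genes with roles in memory or Kenyon cells, Pka-C1, a protein kinase A catalytic subunit (log2 −0.88, adjusted p = 0.0159), 14-3-3zeta (log2 −0.84, adjusted p = 0.0164) and the vesicular transporter gene prt (log2 −1.29, adjusted p = 0.0254) fell. Hsp70Bb, a heat shock gene with near-identical copies, fell from 784 ± 147 to 143 ± 24.7 CPM (log2 −2.45, SE 0.34, adjusted p = 0.00174), the cytoskeletal actin gene Act5C by 1.00 (adjusted p = 0.00211) and the pro-apoptotic gene hid by 2.12 (adjusted p = 0.0431, and log2 −2.80 without juvenile knockdown 1). With upper-quartile scaling the call of prt ended (0.0527).

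MFS3 (log2 −2.44, adjusted p = 0.00395) and Ldh (log2 −1.84, adjusted p = 0.0138) fell in juvenile flies too, and Xxylt rose (log2 0.76, adjusted p = 0.0159). Further decreases included Pop1 (log2 −2.52, adjusted p = 0.00607), the ribosomal protein genes RpLP0 (log2 −0.84, adjusted p = 0.0104) and RpS29 (log2 −0.94, adjusted p = 0.0159), the eye protein kinase C gene inaC, which fell by 1.00 on the log2 scale (SE 0.24, adjusted p = 0.0224), and the activity-regulated nuclear receptor gene Hr38 (log2 −0.80, adjusted p = 0.0366, and 0.0732 with upper-quartile scaling). The esterase gene Est-6 rose from 6.96 ± 2.51 to 25.3 ± 2.76 CPM (log2 1.86, SE 0.29, adjusted p = 0.00207). The lipid droplet gene Lsd-1 (log2 1.01, adjusted p = 0.0133), the diacylglycerol kinase gene rdgA (log2 0.74, adjusted p = 0.0255), the serotonin receptor gene 5-HT2B (log2 0.71, adjusted p = 0.0212), the ecdysone-response gene Eip78C (log2 0.55, adjusted p = 0.0391), Obp56d (log2 1.56, adjusted p = 0.0481) and the axon guidance genes beat-Ia (log2 0.71, adjusted p = 0.0448) and sli (log2 0.53, adjusted p = 0.048) rose. Csp, MFS3, RpS29, Eip78C, sli, 5-HT2B and rdgA overlap other genes on the same strand.

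The juvenile genes named here were separated completely between the 2 knockdown and 3 control libraries, which chance gives for 20% of unselected genes. Having been chosen by their test between these libraries, they gain no support from it. Each of those above was also called in a fit on the 5 juvenile libraries alone, Ldh with adjusted p = 0.00457 and Xxylt with 0.0207. Others were called with all libraries and not in that fit: the POU factor gene nub (log2 −2.76, or −3.62 without juvenile knockdown 1, adjusted p = 0.0262, and 0.095 in the juvenile fit), the neuropeptide gene SIFa (log2 −2.45, adjusted p = 0.014, and 0.069 in the juvenile fit), the caspase gene Drice (log2 −0.74, adjusted p = 0.0326, 0.103 in the juvenile fit and 0.0601 with upper-quartile scaling), topi (log2 2.02, adjusted p = 0.0221, and 0.0948 in the juvenile fit) and the gustatory receptor gene Gr66a (log2 1.70, adjusted p = 0.031, and 0.194 in the juvenile fit).

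In total edgeR called 640 genes in juvenile flies, 185 higher and 455 lower, against 2613 at an unadjusted p under 0.05. Of these, 239 (37.3%; 172 lower and 67 higher) were also called from the juvenile libraries alone. In simulated data in which each age kept its own spread, 56.6% of the calls of the same kind were unchanged genes. That share depends on the number of genes changed in the simulation, so it does not estimate the share among these 640. When both ages were given 1 shared spread, unlike the real libraries, it was 5.3%. DESeq2 called 1266 genes (579 higher and 687 lower) and limma-voom with sample weights 10. That alternative ended 31 of the 33 named juvenile calls and kept those of nub (adjusted p = 0.0302) and Pop1 (0.0316). The split was 281 higher and 335 lower with RLE scaling and 314 and 234 with upper-quartile scaling, which moved the median of all genes by 0.11. The count was 257 without juvenile knockdown 1, 411 without juvenile knockdown 2, 985 without juvenile control 1, 415 without mature control 3 and 420 without mature knockdown 5.

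Of the 33 juvenile genes named, 7 kept their calls whichever library was left out: Act5C, Est-6, Hsp70Bb, nrv2, Pop1, Syt4 and Syngr. Leaving out juvenile knockdown 2 ended 22 of the calls (adjusted p up to 0.295), juvenile knockdown 1 ended 20 (0.302), and juvenile controls 2, 3 and 1 ended 11 (0.1), 8 (0.108) and 3 (0.051). Mature controls 1 to 5 ended 3 (0.0608), 4 (0.0597), 6 (0.0636), 1 (0.0611) and 3 (0.0585), and mature knockdown libraries 2 to 5 ended 4 (0.0619), 2 (0.0612), 5 (0.0618) and 4 (0.0668).

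Some groups of neuronal genes lay lower in juvenile knockdown flies and others did not, while fat body markers lay higher. Cytosolic ribosomal protein genes (4 of 80 lower and 1 higher, median log2 −0.34, adjusted p = 8.45e-06), Kenyon cell markers (3 of 16 lower, median −0.47, 1.93e-05), learning and memory genes (4 of 27 lower, median −0.42, 0.00205), photoreceptor markers (1 of 16 lower and 1 higher, median −0.33, 0.0295) and synaptic machinery (7 of 29 lower, 0.00476) ranked lower in camera, each with adjusted p = 0.817 with an estimated correlation. The median of synaptic machinery was −0.09 and turned to 0.02 with upper-quartile scaling. Cell death genes, with hid and Drice lower, gave adjusted p = 0.00651, and adjusted p = 0.302 with an estimated correlation. SWI/SNF subunits gave 0.0477, and adjusted p = 0.817 with an estimated correlation, but 0.0734 with RLE scaling, and Act5C was their 1 called member. Their list holds Bap60, the target of the RNAi, and was not tested without it. Fat body markers, with Lsd-1 among 2 of 15 higher, had a median of 1.01 (adjusted p = 3.41e-04, and adjusted p = 0.493 with an estimated correlation).

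Adjusted over the list alone, 7 ribosomal, 6 Kenyon cell, 6 learning and memory, 7 photoreceptor and 7 synaptic genes were lower. In the other direction, 1 ribosomal and 1 photoreceptor gene were higher, and 3 fat body genes were higher. Glial (adjusted p = 0.125) and muscle markers (0.281), activity-regulated genes (0.153), ecdysone response genes (0.281) and clock genes (0.665) did not pass. Among neuronal groups, neurotransmitter receptors (0.878; 2 of 34 higher, and 6 higher and 2 lower over the list alone), voltage-gated and leak channels (0.63), neuropeptides (0.397; 3 higher and 4 lower), axon guidance genes (0.397; 2 higher and 1 lower) and markers of other neurons (0.475) did not pass either. SWI/SNF subunits lost their call without juvenile knockdown 1 (adjusted p = 0.238), juvenile control 2 (0.143) or 3 (0.1) or mature control 2 (0.0501), and cell death genes without juvenile knockdown 1 (0.0891). Without juvenile knockdown 2 the calls of learning and memory genes (0.0718), photoreceptor markers (0.337) and synaptic machinery (0.186) were lost, and without juvenile control 2 the same lists gave 0.118, 0.0571 and 0.164. Photoreceptor markers also lost theirs without juvenile control 1 (0.193).

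**Figure D4:**
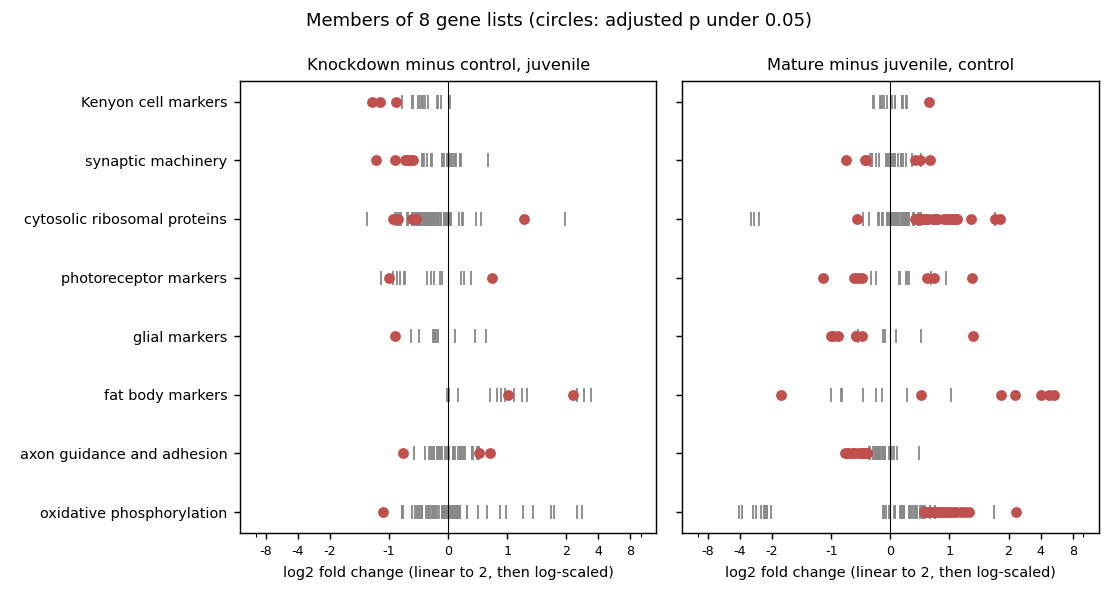
Log2 fold change of the members of 8 gene lists after Bap60 knockdown in juvenile flies (left) and from juvenile to mature controls (right). Circles mark members with an adjusted p under 0.05 over all genes.

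Whether Bap60 knockdown acted differently at the 2 ages was tested as the juvenile minus the mature effect. Some neuropeptide and synaptic genes had a more negative log2 effect in juvenile than in mature flies. They were AstC (log2 difference −2.06, SE 0.33, adjusted p = 0.00657), sNPF (−1.39, 0.0164), Ms (−1.37, 0.0221), Syngr (−1.20, 0.0106), Syt4 (−1.02, 0.0105) and Rop (−0.86, 0.0208). The same held for nrv2 (−1.07, 0.00657), Act5C (−0.90, 0.0208), inaC (−1.21, 0.0373), Hsp70Bb (−1.64, 0.046) and the glutathione transferase genes GstE1 (−2.02, 0.0113) and GstD11 (−2.04, 0.0249). The zinc finger gene salm was at 34 ± 15.5 CPM in juvenile knockdown and 112 ± 13.8 CPM in juvenile control libraries, against 22 ± 2.86 and 19.7 ± 3.15 CPM in mature ones (−1.88, SE 0.29, adjusted p = 0.00657, and −2.47 without juvenile knockdown 1). Est-6 (1.78, 0.0176), the transporter gene Mct1 (1.24, 0.0238), Lsd-1 (1.18, 0.0325) and the nuclear receptor gene Hr4 (1.12, 0.0352) had a more positive log2 effect in juvenile than in mature flies. Upper-quartile scaling ended the calls of Act5C (0.0665), Rop (0.0669), inaC (0.0683), Ms (0.0536), Hsp70Bb (0.106) and GstD11 (0.0511), and RLE scaling those of inaC and Hsp70Bb (0.0587 for each).

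The difference was called for 186 genes, 33 higher and 153 lower, against 1955 at an unadjusted p under 0.05. In simulation with a separate spread for each age 31.4% of such calls were unchanged genes, a share that also depends on the number of genes changed. DESeq2 called 561 (212 higher and 349 lower), limma-voom with sample weights 7, among the named genes only salm (adjusted p = 0.0329), and upper-quartile scaling gave 38 higher and 64 lower and moved the median of all genes by 0.109. The count was 108 without juvenile knockdown 1, 457 without juvenile control 1, 111 without mature control 3, 117 without mature control 5 and 91 without mature knockdown 5. AstC, nrv2, Syt4, salm and GstE1 kept their calls with any library left out. Of the 17 named genes, juvenile knockdown 2 ended 11 calls (adjusted p up to 0.14), juvenile knockdown 1 ended 8 (0.11), juvenile controls 1 to 3 ended 1 (0.0613), 5 (0.0823) and 3 (0.0754), mature controls 1 to 5 ended 1 (0.0506), 3 (0.0792), 3 (0.0728), 2 (0.0634) and 2 (0.0807), and mature knockdown libraries 1 to 5 ended 1 (0.0583), 1 (0.0558), 1 (0.0772), 3 (0.0572) and 4 (0.0741).

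Ribosomal protein genes (adjusted p = 1.21e-06), Kenyon cell markers (1.81e-06), synaptic machinery (5 of 29 members lower) and learning and memory genes (both 4.85e-06), photoreceptor markers (2.42e-04), neuropeptides (3 of 26 lower, 0.00657), glial markers (0.00809), markers of other neurons (0.0148), neurotransmitter receptors (0.0358) and mitochondrially encoded genes (0.042) ranked lower in the difference. Fat body markers (0.00151) and cuticle proteins (0.0038) ranked higher. With an estimated correlation the lowest of these was adjusted p = 0.537. Adjusted over the list alone, 7 synaptic, 7 learning and memory, 7 neuropeptide, 5 Kenyon cell and 4 photoreceptor genes were lower. By the same measure 1 neuropeptide gene and 4 fat body genes were higher.

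Receptors lost their call with RLE scaling (adjusted p = 0.0594) and without juvenile knockdown 1 (0.0526) or 2 (0.136), juvenile control 2 (0.355) or 3 (0.0905), mature control 2 (0.159) or mature knockdown 1 (0.054) or 3 (0.135). Mitochondrially encoded genes lost theirs without juvenile knockdown 1 (0.131) or 2 (0.0796), juvenile control 1 (0.208), mature control 1 (0.152) or mature knockdown 2 (0.0808), 3 (0.0757) or 4 (0.0691). Without juvenile knockdown 1, fat body markers (0.0823) and cuticle proteins (0.0583) were not called, and without juvenile control 1 the markers of other neurons (0.0638) were not.

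Ldh, MFS3 and Xxylt were called at both ages in the same direction. By chance 0.031 shared higher genes and 0.19 shared lower genes were expected against 1 and 2 found (Fisher's exact test, one-sided, p = 0.0306 and 0.0133). All 7 genes called in mature flies had the same sign in juvenile flies, as did 368 of the 640 juvenile genes (57.5%) in mature flies, against 50.4% of all genes. Across 11997 genes, which are not independent replicates, the 2 effects had a Pearson correlation of −0.064 and a Spearman correlation of −0.022, and 0.098 and 0.118 over the 6650 genes of at least 5 CPM.

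Among controls, the change from newly eclosed to mature flies included genes of fat, respiration, ribosomes and receptors. The libraries also held RNA of other cell types, as with the photoreceptor gene ninaE at 2680 to 7190 CPM in mature controls. Whether the share of other cells differed between ages was not tested, so these changes need not be changes within Kenyon cells. Of the 15 fat body markers 6 rose and 1 fell. Those that rose included the lipid carrier gene apolpp (144 ± 29.7 to 2300 ± 277 CPM, SE 0.22 on the log2 scale, adjusted p = 3.34e-09), the transferrin gene Tsf1 (log2 1.88, 2.27e-05), to (log2 4.83, 2.94e-05), and the storage protein gene Lsp2 (log2 5.33, 0.00122). Gnmt (log2 4.79, 0.00137) and the cytochrome P450 gene Cyp4d21 (log2 4.11, 0.00372) rose as well. These folds rest on low counts in at least 1 juvenile control: without juvenile control 3 the value was 4.24 for to and 11.7 for Lsp2, which then had 0 counts in juvenile controls, and without juvenile control 1 it was 7.39 for Gnmt and 5.70 for Cyp4d21. The complex I genes ND-51 (log2 1.33, 7.06e-05), ND-24 (log2 1.19, 1.53e-04) and ND-75 (log2 1.00, 6.56e-04), the ribosomal protein genes RpS18 (log2 1.77, 9.13e-07) and RpL5 (log2 1.02, 7.46e-05) and Obp99c (log2 1.99, 2.50e-05) also rose. Of the SWI/SNF genes, Bap60 (log2 0.87, SE 0.27, 0.0256), the ATPase gene brm (log2 0.93, 3.23e-05) and Bap111 (log2 0.91, 0.0032) rose and Act5C fell (log2 −0.69, 4.59e-04). In camera the SWI/SNF list was not called (adjusted p = 0.055), with 5 of 12 higher and 1 lower. Leaving out any 1 of 6 libraries gave it a call. The Bap60 call was lost without juvenile control 2 (adjusted p = 0.097) or mature control 1 (0.0553).

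Genes that fell with age included nub (113 ± 34.2 to 4.32 ± 2.64 CPM, log2 −4.69, adjusted p = 2.80e-05), Doc1 (log2 −3.64, 9.77e-06), the cuticle genes Cpr76Bd (log2 −2.13, 1.58e-05) and Cpr49Ac (log2 −3.55, 0.0174, and −4.19 without mature control 3), Mur18B (log2 −4.39, 0.00181), the channel gene ppk22 (log2 −3.86, 0.0169, and −4.91 without mature control 4), the mitotic kinase gene polo (log2 −3.18, 0.00548), and the adhesion and guidance genes Ten-m (log2 −0.72, 5.05e-05), Fas3 (log2 −0.77, 3.69e-04) and Sema1b (log2 −0.63, 1.98e-04). Cuticle proteins as a list were not called (adjusted p = 0.484), with 6 higher and 9 lower. Nor were ecdysone response genes in camera (adjusted p = 0.0998), with 3 of 23 higher and 6 lower, except without juvenile control 1 (0.0353) or mature control 4 (0.0325). The cell death genes hid (log2 −2.51, 7.60e-04) and Drice (log2 −1.15, 3.40e-05) and the ecdysone-induced genes Eip74EF (log2 −1.40, 0.00193) and Eip75B (log2 −0.61, 0.00182) fell. So did the receptor genes 5-HT2A (log2 −0.87, 1.91e-04), Octbeta2R (log2 −0.74, 0.0017), nAChRbeta2 (log2 −0.66, 3.65e-04) and mGluR (log2 −0.70, 0.00254), the glial genes bdl (log2 −1.01, 1.68e-05) and Gs2 (log2 −0.88, 6.39e-04), the tyrosine hydroxylase gene ple (log2 −2.48, 0.0221), the neuropeptide gene CCHa1 (log2 −2.33, 4.47e-04), and chp, nrv2, Syngr and BomS2. Of the near-identical heat shock genes Hsp70Bb fell (log2 −1.14, adjusted p = 0.00341) and Hsp70Ab rose (log2 4.20, adjusted p = 0.0258, and 0.343 with limma-voom), so both are uncertain. The Hsp70Ab call was lost without juvenile control 1 (0.0694), 2 (0.0749) or 3 (0.0579), and stress response genes as a list were not called (0.136; 3 higher and 4 lower), though they were without mature control 4 (0.0325) or mature knockdown 3 (0.0463). The activity-regulated gene sr (log2 0.95, 9.78e-05) and CG14186 (log2 0.70, 0.00431), the clock gene cry (log2 1.15, 2.35e-04), ninaE, Xbp1, Xrp1 and dl rose.

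The called genes named here were separated completely between the 5 mature and 3 juvenile controls, which chance gives for 3.57% of unselected genes. They were chosen by their test between these libraries and are a subset of those the rule gave, so the separation is no further support. For ple, limma-voom with sample weights gave adjusted p = 0.0566. In all 2644 genes were called, 1460 higher and 1184 lower in mature flies, but more were lower than higher with RLE scaling (1230 higher and 1432 lower) and in DESeq2 (1525 and 1661). Oxidative phosphorylation genes (31 of 75 higher and none lower, median 0.57, adjusted p = 6.02e-06), ribosomal protein genes (25 of 80 higher and 1 lower, 7.48e-05), fat body markers (6 of 15 higher and 1 lower, 6.05e-04), odorant-binding proteins (9 of 32 higher and 1 lower, 0.0128) and activity-regulated genes (4 of 11 higher, 0.0195) ranked higher. Axon guidance genes (14 of 41 lower, 9.21e-06), receptors (8 of 34 lower and 1 higher, 0.00214), glial markers (6 of 12 lower and 1 higher, 0.00866), cell death genes (7 of 13 lower and 1 higher, 0.0128) and neuroblast and cell cycle genes (3 of 16 lower, 0.0195) ranked lower.

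With an estimated correlation these lists gave adjusted p = 0.481 for fat body, odorant-binding and activity-regulated genes, adjusted p = 0.401 for cell death genes and 0.697 for the rest. Adjusted over the list alone, 34 oxidative phosphorylation genes were higher and 1 lower, 27 ribosomal genes were higher and 1 lower, 16 axon guidance genes were lower and 1 higher, and 10 receptor genes were lower and 2 higher. The median of ribosomal protein genes, 0.261, lay at percentile 78.05 among random lists matched on exon length and expression (central 95%, 0.053 to 0.349), and that of oxidative phosphorylation genes, 0.569, at percentile 99.99 (−0.132 to 0.255). Activity-regulated genes (adjusted p = 0.119) and neuroblast genes (0.181) lost their calls without juvenile control 1, and receptors without juvenile control 2 (0.12). The medians of Kenyon cell markers and synaptic machinery, which were not called, changed sign with RLE scaling.

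Between juvenile and mature knockdown flies 4104 genes were called, 2136 higher and 1968 lower in mature flies, and 2516 without juvenile knockdown 1. More were lower than higher with RLE scaling (1681 higher and 2249 lower), with upper-quartile scaling (1649 and 2219) and in DESeq2 (1945 and 2206). RLE scaling moved the median of all genes by −0.114. Ribosomal protein genes (50 of 80 higher, adjusted p = 9.03e-12), oxidative phosphorylation genes (44 of 75 higher and 4 lower, 1.18e-06), Kenyon cell markers (8 of 16 higher, 0.0019), synaptic machinery (11 of 29 higher and 2 lower, 0.00466), SWI/SNF subunits (7 of 12 higher, 0.0048), activity-regulated genes (0.0107), mitochondrially encoded genes (0.0184), photoreceptor markers (0.0222), learning and memory genes (0.0294) and neuropeptides (0.034) ranked higher. Axon guidance genes (0.00574), cuticle proteins (0.0098) and neuroblast genes (0.034) ranked lower. With an estimated correlation adjusted p = 0.703 for learning and memory genes and 0.692 for the others. Without juvenile knockdown 1 axon guidance genes gave 0.0642, and without juvenile knockdown 2 learning and memory genes gave 0.109, photoreceptor markers 0.132, neuropeptides 0.0907 and neuroblast genes 0.0631. Without mature knockdown 3 learning and memory genes gave 0.0706 and neuropeptides 0.0831. With RLE scaling learning and memory genes gave 0.0552 and neuroblast genes 0.0531. Adjusted over the list alone, 52 ribosomal genes were higher and 1 lower, and 46 oxidative phosphorylation genes were higher and 6 lower.

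The knockdown effects were also set against the age difference in controls over the 6650 genes of at least 5 CPM. Genes are not independent replicates, and the comparisons share control libraries. The juvenile effect had r = 0.168 and a covariance of 0.0626. Libraries simulated with neither a knockdown nor an age effect gave 0.518 and 0.0728. The mature effect had r = 0.227 and a covariance of 0.0433, where such libraries gave −0.318 and −0.0222. The simulated age difference was noise alone, so the simulated r sets no level for the observed r. With separate control libraries on the 2 sides the mean r was 0.021 (0.001 to 0.032) for the juvenile and 0.26 (0.223 to 0.302) for the mature effect. These ranges are over splits, each averaged over its 2 orientations. Of the juvenile genes, 83 higher and 110 lower ones were also called in the same direction with age, against 22.5 and 44.9 for independent lists. Simulations with no effect gave overlaps of 3.2 and 0.3, but their age lists held only 4.4 higher and 1.4 lower genes, so these overlaps set no level for the observed ones.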

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

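The tests of spread, of cell composition and of depth, and those of the mitochondrial level and of the listed features, were chosen only after the result was seen. The length tests and the splits of the samples were planned, though the length test of the age difference was first written for both gene groups as 1 test and parted afterwards, and the rule for the depth test was changed once its value was known. Under the earlier rule, on r from all libraries alone, depth would have been argued against.

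In juvenile flies 640 genes were called, and 37.3% of them were called from the juvenile libraries alone. The wider spread of these libraries may account for part of the list, but this share cannot show it. With 1 spread shared by both ages in simulation, the fit on all libraries recovered 56.7% of 2-fold and 92.3% of 4-fold changes. The fit on the juvenile libraries alone recovered 29.3% and 86.3%, so a smaller fit loses calls without a wider spread. Bias by exon length as the whole cause is argued against, since at least 99.9% of the median log2 fold change stayed after a trend on exon length was taken out of each library. Whether introns were counted is not known, and bias by the full span of genes was not tested. Of the called genes, 372 of 455 lower and 156 of 185 higher ones were still called then. A lower share of Kenyon cell nuclei, with the other nuclei in an unchanged mix, would raise fat body and photoreceptor markers alike. The level of the first minus the second was higher in both knockdown libraries (−2.54 and −2.75) than in the controls (−3.82, −3.85 and −3.71). The gap was 0.96 on the log2 scale. Kenyon cell markers were at a lower level in both knockdown libraries (9.22 and 9.24) than in the controls (9.43, 9.94 and 9.82). A lower share of Kenyon cell nuclei in which the mix of the other nuclei also changed is therefore not excluded. It stays open, as do a change in the fat body cells themselves and an effect of the knockdown on the genes.

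Counts of the UNC84 tag, which no comparison of the report used, were at least 109399 in each mature library. They came to 6340 ± 1690 per 1e6 gene counts in the knockdown and 10800 ± 3670 in the control libraries (SD, n = 5 each), a log2 difference of −0.75 with a two-sided exact permutation p = 0.024, and −0.69 with p = 0.032 after TMM scaling. A lower share of Kenyon cell nuclei as the whole cause is argued against, as far as the Kenyon cell markers track that share. The median of 16 such markers lay 0.71 above the change of the tag, beside an SD of 0.09 across the markers. That SD does not measure the spread between libraries, and the tag ran from 7049 to 15694 per 1e6 within the controls. A difference in depth cannot be told apart with these libraries: the tag and the total count had a within-group Pearson r of 0.24 (permutation p = 0.615) and a Spearman rho of 0.14 (p = 0.74) over 10 libraries, r ran from −0.18 to 0.47 with 1 library left out, and r was −0.41 without the 2 libraries farthest from the median total. An effect of the knockdown on the tag transgene may be a cause and was not tested.

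Oxidative phosphorylation and ribosomal protein genes were higher in mature than in juvenile controls, with adjusted p = 0.697 for both lists with an estimated correlation. Bias by exon length is argued against for the first, whose median lay at percentile 99.99 of random lists matched on exon length and expression. It may account for the second, at percentile 78.05. Bias by the full span of genes was not tested. More cytoplasmic RNA in mature libraries stays open, since the level of mitochondrially encoded genes in the lowest mature control minus that in the highest juvenile control was −1.22, with mature control 1 at 5.05. Processing that differed between ages cannot be told apart from age, since the files of the 2 ages differed by 1 listed feature, the tag. A share of other cells that differed between ages was not tested. Age itself stays open as the cause.

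Other splits of the samples bear on the counts of called genes. For the 7 genes of the mature comparison, 4 of 100 splits drawn from 126, the real one included, called as many. That share is under 0.05 among the splits drawn, but the rest were not run and could move it, so whether chance can be excluded stays open. The highest other splits called 54 and 49, several times the real count. Both put mature knockdown 1 and mature controls 1 and 5 on the same side. In some gene lists mature control 1 and mature knockdown 1 lay together, apart from the other mature libraries. Their mitochondrially encoded levels were 5.05 and 5.33 (6.51 to 7.07 in the others). Muscle marker levels were 6.7 and 6.78 (7.69 to 9.13) and SWI/SNF levels 6.22 and 6.28 (5.86 to 6.06). A structure other than genotype was thus present in these libraries. Whether it or chance gave these counts was not tested. For the 2644 genes of the age comparison 1 of 56 splits, the real one, called as many, and the highest other called 216. That share, the smallest these splits allow, is under 0.05, so a chance split of the libraries is argued against. It does not separate age from processing or anything else that went with age.

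Of 230 groups of values, 11 held a library far from the others, where 11.5 are expected by chance, and 6 of the 11 were in mature knockdown 1. Mature knockdown 1 had a SWI/SNF level of 6.28 (5.86 to 5.94 in the others), a mitochondrially encoded level of 5.33 (6.63 to 6.78), and CPM values of 202 for prt (116 to 138), 377 for rdgA (529 to 577), 37.8 for GstD11 (16.9 to 20.6) and 341 for CG14186 (212 to 245). Mature knockdown 3 had 33.4 CPM of Hsp70Ab (1.87 to 9.59). Mature knockdown 5 had 37.7 CPM of Ms (24.3 to 27.3). Mature control 1 had a mitochondrially encoded level of 5.05 (6.51 to 7.07), mature control 2 had 7190 CPM of ninaE (2680 to 3770), and mature control 3 had a total of 70.5 in units of 1e6 counts (18.2 to 32.8).

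The knockdown effect differed between ages for 186 genes in edgeR's test of the difference. Those named were AstC (log2 −2.06), GstD11 (−2.04), GstE1 (−2.02), salm (−1.88), Hsp70Bb (−1.64), sNPF (−1.39), Ms (−1.37), inaC (−1.21), Syngr (−1.20), nrv2 (−1.07), Syt4 (−1.02), Act5C (−0.90), Rop (−0.86), Hr4 (1.12), Lsd-1 (1.18), Mct1 (1.24) and Est-6 (1.78).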

How the results depend on the processing

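Voom weights by age and the Kenyon cell marker level as a covariate were chosen only after the result was seen, and the other alternatives were planned. Of the values of named genes under all alternatives, 2690 kept direction and side of the threshold, 403 lost the call, none gained one and 5 reversed. The reversed ones were the age difference of the Bap60 effect, which was never called: −0.03 with 1 surrogate variable, −0.29 without juvenile knockdown 2, −0.25 without juvenile control 2, −0.05 without mature control 1 and −0.09 without mature knockdown 3, with a range of −0.29 to 0.3 over left-out libraries. Why the counts moved was not tested.

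Genes called in juvenile flies were 1266 with DESeq2, 10 with voom and sample weights, 4 with voom weights by age, 387 with only the groups compared, 1119 with 1 surrogate variable, 213 against a 1.2-fold change, 143 at an adjusted p under 0.01, and 257 to 985 with 1 library left out. In mature flies they were 47, 114, 33, 13 and 15 under the first 5 of these, 33 with the Kenyon covariate, 3 at 0.01 and 3 to 11 with 1 library left out. That covariate gave 604 in juvenile flies, 288 of them among the 640, and 225 for the difference, 94 of them among the 186, and it ended 12 of the named juvenile and 8 of the named difference calls. For the difference they were 561, 7 and 0 with DESeq2 and the 2 voom fits (1405 at an unadjusted p under 0.05 for the last), 102 with upper-quartile scaling, 290 with 1 surrogate variable, 67 against 1.2-fold, 21 at 0.01 and 91 to 457 with 1 library left out, and a fit on only the groups compared was not possible. For age in controls they were 1668 and 1360 with the 2 voom fits, 1718 against 1.2-fold, 1407 at 0.01 and 2023 to 2721 with 1 left out, and for age in knockdown flies 1947 with the Kenyon covariate, 2280 at 0.01 and 2516 to 4640.

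With the replicate number as a block the counts were 1054 in juvenile flies, 16 in mature flies and 487 for the difference, and with the block and 1 surrogate variable 2805, 81 and 1807. The block alone kept 529 of the 640, 6 of the 7 and 168 of the 186 main calls. It ended 4 of the named juvenile calls and 1 of the named mature calls. The numbers were not taken as pairs, which would need a correlation over 0.1 in every pair: correlations of same-numbered libraries were −0.031 and 0.013 in juvenile and −0.003 to 0.275 in mature flies, and 3 of 5 mature and 0 of 2 juvenile knockdown libraries correlated best with their own number. Mature control 1 and mature knockdown 1 had the highest of these, 0.275. A rule over every pair does not exclude that these libraries belonged together. The block was not run for the age comparisons.

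With an estimated correlation camera called 0 lists in each of the 5 comparisons, against 8, 14, 12, 10 and 13 with the preset one, and fry called 1 in juvenile flies, 0 in mature flies, 0 for the difference, 9 for age in controls and 13 for age in knockdown flies. With 1 library left out camera called 4 to 9, 14 to 16, 8 to 14, 10 to 13 and 10 to 14. Genes called at both ages were 3, and 14 with DESeq2 and 1 with voom. The relation to the age difference was 0.324 (juvenile) and 0.309 (mature) over genes called with age, and 0.021 and 0.26 with separate controls.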

Other observations

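The test of the age axis in juvenile flies was chosen only after the result was seen.

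That juvenile knockdown libraries are shifted along the age difference of controls was a hypothesis. With separate juvenile controls on the 2 sides the mean correlation across genes was 0.021, so the test gave no sign of a shift. It cannot exclude one, since each split was averaged over its 2 orientations and each side held 1 or 2 juvenile controls. The biological coefficient of variation was 0.85 in juvenile and 0.22 in mature libraries, so the values of the 2 ages are not alike in precision. In mature flies the same measure was 0.26, and a shift of the knockdown libraries along the age difference may be a cause there. The flies of the mature group were 1 to 5 days old, and a difference in age between the genotypes within that range was not tested.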
